A study of Mus musculus with 2 samples.

How the data were processed

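H3K9ac ChIP-seq was measured in 2 biological replicates of embryonic day 11.5 mouse heart, which form the only group. Per the labels, each replicate is pooled tissue of both sexes, the replicates are biological, the fragments sequenced were 300 to 500 bp and the assembly is mm10. The labels list a separate tissue sample for each replicate and do not say how the dissections were divided, so differences between them may in part be technical.

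The deposited files are 4 narrowPeak lists. Per the authors' descriptions deposited with the files, each replicate's list was made from that replicate's filtered alignments with further input files, the pooled list from both replicates, and the replicated list from the pooled list and both replicates' own lists. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak are not given in the sources used here. The deposited display score was not used in any result. The deposited signal value was read as a fold of ChIP over control. The authors' files do not name its unit, and this reading rests on the format and on values that start at 1.74. The deposited −log10 p and −log10 q of each peak were used only for filters and ranks. The deposited summit offset, another value per peak, was not used. No list holds read counts, so depth is unknown, and a peak missing from a list may be a region below the authors' threshold.

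Peaks on chromosomes 1 to 19, X and Y were used (81124, 90541, 65175 and 44560 for replicate 1, replicate 2, the pooled and the replicated list). Peaks on unplaced sequences (9, 6, 7 and 6) were left out. Median widths were 274, 266, 327 and 485 bp, and the lists covered 41.5, 40.3, 39.0 and 34.2 Mb. The lowest −log10 p was 2.01, 2.01, 2.04 and 2.05. The reference was GRCm38, the assembly also called mm10, with GENCODE M21 gene annotation, and all peaks lay within its chromosome lengths. RefSeq annotation of the same assembly was used for a single test.

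Overlap between lists was at least 1 bp, and the random value came from 100 placements of the other list within chromosomes with bedtools shuffle (bedtools 2.31.1, no overlap among placed peaks, assembly gaps not excluded). A gene had a promoter peak if a replicated peak lay within 1000 bp of any of its annotated transcript starts (93513 starts of 21938 protein-coding genes), and its fold was the highest among such peaks. Acetylated length was the number of bp covered by peaks within 5000 bp of the 5'-most start, over genes with a promoter peak. It misses genes that use other starts. A distal peak lay more than 2500 bp from every annotated start of any gene and was given to the protein-coding start nearest to its midpoint within 100 kb. That start need not belong to the gene it regulates.

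In all, 23 gene lists were written before the data were examined, and olfactory receptors were added by symbol. They hold 482 distinct genes, of which 4 are in more than 1 list, and 1 gene (Ahsp) was not found in the annotation. Shares of genes with a promoter peak were tested against all other protein-coding genes with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 24 lists (threshold 0.05). Fold, acetylated length and distal peak number were set against 10000 random lists of the same size, drawn with replacement from genes with a promoter peak or, for distal peaks, from genes in the same decile of interval length. The plan gave percentiles. Two-sided p-values of the same random lists, adjusted over lists, were added after the data were examined, and the smallest unadjusted value is 0.0002. Random lists in the alternatives were matched on the decile of promoter CpG observed to expected ratio, 1000 bp either side of the 5'-most start. Genes are not replicates of a tissue, so these tests describe the gene lists within this peak set, with no replicate error. Genes that share a promoter peak were counted separately in the main results.

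Genes were named by a rule fixed before the data were examined: 18 named in advance, the 10 highest promoter folds, the 10 longest, the 10 with most distal peaks, the nearest genes of the 10 strongest distal peaks, up to 4 strongest and 3 absent members of each list, and the 5 strongest unshared promoter peaks of each replicate. The alternatives were overlap of 50%, −log10 q of at least 2 or 5, the 20000 strongest peaks, windows of 500, 2500 and 10000 bp, a distance of 50 kb, the 5'-most start, the pooled list, each replicate's own list and CpG-matched lists. Without replicate 1 means in replicate 2's own list (90541 peaks), and without replicate 2 in replicate 1's own list (81124 peaks). Both hold more peaks than the replicated list (44560), so changes in these settings need not come from the replicate left out. A setting with only peaks overlapped in both replicates' own lists and a setting without genes that share a peak were added after the data were examined.

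The code was tested on simulated data. Its overlap counts equalled those of bedtools in 4 of 4 settings. Of 800 simulated lists with a peak at exactly 23 of 25 genes, 100% were called by the share test over 21938 genes. All held the same counts, so this outcome was fixed in advance and measures no power. Of 1600 random lists, 1.5% were called. For acetylated length 4.5% of 200 random lists and 99.5% of 200 lists of doubled length passed an unadjusted 0.05, and for distal peaks 4.5% of 200 random lists did. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

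Motifs were searched on both strands in windows of 500 bp around the midpoints of 17100 of 17290 distal peaks and in as many windows of the same chromosomes, each over 5000 bp from any pooled peak and matched on GC content in bins of 2% (mean GC 52.1% and 52.0%). Repeats were not excluded. The shares of windows with a motif were compared with two-sided Fisher's exact tests adjusted over 11 motifs, and their ratios have 95% intervals from the normal approximation on the log scale. Shares of genes or peaks in the tests of explanations have exact 95% binomial intervals, which cover counting error only, and the interval of a median CpG ratio is from order statistics.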

Results

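H3K9ac, an acetylation of histone H3 found at active promoters and at many enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole heart tissue from mouse embryos at embryonic day 11.5. At this stage the looped heart beats and holds forming chambers, cushions and an outflow tract. The tissue came from pooled embryos of both sexes of the B6NCrl strain. The dataset had 1 group of 2 biological replicates and no second tissue, age or treatment. The comparisons it allows are replicate against replicate and, within the heart, gene group against gene group. Replicate 1 had 81133 peaks and replicate 2 had 90547 peaks. A list called on both replicates pooled had 65182 peaks, and a list of replicated peaks had 44566. The lists carry no read counts, so sequencing depth per replicate is unknown and no counting interval was set on any peak. Each peak's fold over control is the authors' own value, and ranks in lists of different lengths show no change.

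Among cardiac regulators and contractile genes, several named in advance had promoter peaks of high fold in both replicates, and others, such as Isl1 (8.43 and 5.46), lower ones. Nkx2-5, a homeodomain factor of cardiac progenitors, had a promoter peak of fold 30.2 in replicate 1 and 24.9 in replicate 2, at an internal annotated start, and 11.7 and 14.2 at its 5'-most start. Gata4, a zinc finger factor of cardiac mesoderm, had 33.9 and 29.3, also at an internal start, and 25.8 and 18.8 at its 5'-most start, and Hand2, a basic helix-loop-helix factor of the right ventricle, had 34.2 and 32.7. The contractile genes Tnnt2 (cardiac troponin T) and Actc1 (cardiac alpha-actin) had 28.3 and 21.5, and 20.4 and 18.2. Of the genes of other lineages named in advance, Alb, Myod1 and Neurod1, which mark liver, skeletal muscle and neurons, had no promoter peak in either replicate. Sox10, of the neural crest list, had weak ones (4.13 and 3.96), as did Hbb-y of the erythroid list (4.43 and 3.64).

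Across all peaks, 49.5% of replicate 1 peaks and 48.9% of replicate 2 peaks overlapped a peak of the other replicate by at least 1 bp. Randomly placed peaks overlapped in 3.64% and 3.27% (means of 100 placements; one-sided permutation p = 0.0099 for each, the smallest they can give). By fold, 24.1% of replicate 1 and 23.3% of replicate 2 peaks under fold 3 were overlapped, against 98.4% and 99.5% of those of fold 6 to 10. All 9964 peaks of replicate 1 and all 7557 peaks of replicate 2 with a fold of 10 or more were overlapped. Overlapped peaks had a median width of 500 bp in replicate 1 and 423 bp in replicate 2, against 216 bp and 222 bp for the others, and held 75.4% and 71.5% of the covered length. With peaks of −log10 q of at least 5 only, the overlap was 65.5% of replicate 1 peaks and 90.2% of replicate 2 peaks. With overlap of at least 50% of both peaks it was 32.6% and 29.2%.

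**Figure D1:**
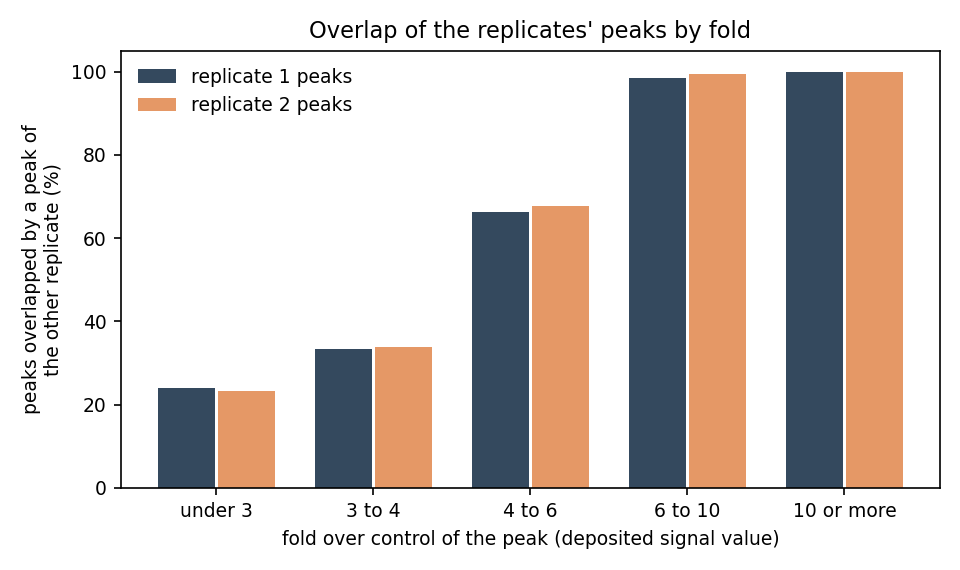
Share of each replicate's peaks (vertical axis, percent) that a peak of the other replicate overlapped by at least 1 bp, by the peak's deposited fold over control (horizontal axis, fold bands); dark bars are replicate 1 and light bars replicate 2. The shares run from 24.1% and 23.3% under fold 3 to 100% in both at a fold of 10 or more.

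Over 37841 pooled peaks with a peak in both replicates, the replicates' folds had a Spearman's rho of 0.788 and a Pearson's r of 0.869 on the log2 scale. These are correlations across peaks, which are not independent replicates, so no p was computed. The log2 ratio of replicate 1 to replicate 2 had a median of 0.18 and an SD of 0.49 across peaks, and 95.4% of the peaks lay within 2-fold. Of the peaks without a partner, 14.5% in replicate 1 and 11.4% in replicate 2 lay at promoters. The strongest of these promoter peaks in replicate 1 lay at Tcf20 (fold 9.74), Rbsn (9.0), Hoxa4 (8.86), Cenpu (8.57) and Cox7a2 (8.50). In replicate 2 they lay at Lims1 (7.12), Ccin (6.92), Cilp2 (6.92), Ctxn1 (6.65) and Cdr2l (6.19). Each of these 10 genes also had a promoter peak in the other replicate. Rbsn, for example, had best promoter peaks of fold 21.8 and 20.5, and Tcf20 of 17.7 and 13.1.

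All 44560 replicated peaks on the main chromosomes were peaks of the pooled list with unchanged borders, and they made up 68.4% of it. Kept peaks had a median fold of 4.19 and dropped peaks 2.92. Of the kept peaks, 83.1% were overlapped by peaks in both replicates' own lists. The remaining 7517 (16.9%) were not, with 5233 overlapped in replicate 1 only, 2183 in replicate 2 only and 0.227% of the list in neither. They had a median fold of 3.27, against 4.73 for the rest, and held 6.59% of the covered length. Of the genes with a promoter peak in the replicated list, 273 had it only among these peaks. Hoxd9, a posterior Hox gene with a replicated promoter peak of fold 3.43, had a promoter peak of 3.26 in replicate 1's own list and none in replicate 2's.

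Replicated peaks concentrated at gene starts. Of 44560 peaks, 46.6% lay within 1000 bp of a protein-coding transcript start, against a mean of 5.28% in 100 random placements (one-sided permutation p = 0.0099, the smallest they can give). These peaks had a median fold of 8.06 and held 68.0% of the covered length. A further 4.36% lay at other annotated starts, 10.2% lay 1000 to 2500 bp from a start, and 38.8% were distal, with a median fold of 3.48. Of the promoter peaks in the replicated list, that of Rbm39, a splicing factor gene, led with fold 47.2 on chromosome 2 (156178709 to 156181555, mm10), followed by the translation elongation factor gene Eef1a1 (44.3), Zc3h4 (41.8), the cytoplasmic actin gene Actg1 (41.0), Hnrnpu (41.0), Naca (40.8), Tardbp (40.4), Pcif1 (40.4), Hipk3 (40.2) and the ribosomal protein gene Rps19 (40.2). The order differed in the replicates' own lists, where Rbm39 had 39.4 and 32.2, Hnrnpu 47.5 and 32.0, and Zc3h4 39.9 and 36.4. With −log10 q of at least 5, 70.5% of the peaks lay at protein-coding starts, and in replicate 1's and replicate 2's own lists 32.1% and 31.4%.

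In all, 14102 of 21938 protein-coding genes (64.3%) had a replicated peak within 1000 bp of a start. The share was 4.42% in the decile of genes with the lowest promoter CpG ratio and 97.8% in the highest. Of the genes with a peak, 10.2% had their strongest one over 1000 bp from their 5'-most start, at another annotated start; among the named genes 27 of 123 did, such as Nkx2-5, Gata4, Eef1a1, Ldha, Igf2 and Ptch1. Folds and orders within lists were taken from the replicated list, and orders can differ in a replicate's own list. Of 13889 genes with a promoter peak in the replicated list and in both replicates' own lists, the fold in replicate 1 was over 1.5 times that in replicate 2 for 3474. The reverse held for 144 (25 and 3 of 122 named genes). Of the genes with a peak, 19.2% shared their strongest promoter peak with another gene, as Hadha and Hadhb did, which encode the subunits of the mitochondrial trifunctional protein and start at a common peak of fold 18.7.

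Heart gene groups held promoter peaks almost throughout. All 25 listed cardiac transcription factor genes and all 25 sarcomere genes had one (adjusted exact p = 7.01e-05 for each). Among the former, Srf, a regulator of muscle genes, had fold 36.8, Hand2 36.2, Gata6 34.5 and Gata4 30.9. Among the latter, Myom1 had 31.3 at a peak it shared with Myl12a and Myl12b, the tropomyosin gene Tpm1 29.1, Tnnt2 25.6 and the atrial light chain gene Myl4 20.2. The share for all other genes was 64.2%. The p of a list's share is from a two-sided Fisher's exact test, adjusted over 24 lists, except against CpG-matched lists, where it comes from 10000 random lists. A gene without a promoter peak here is one without a replicated peak; some of these had a weak peak in a replicate's own list.

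Of the ion handling genes, 23 of 25 had a promoter peak (adjusted exact p = 0.00468), led by the calcium pump gene Atp2a2 (fold 33.7), Gjc1 (26.3), the ryanodine receptor gene Ryr2 (22.5) and the potassium channel gene Kcnh2 (18.3). Among these genes the order was that of replicate 1 (34.6, 28.9, 25.3 and 19.3), where Slc8a1 (20.4) stood above Kcnh2. In replicate 2 Atp2a2 had 18.9, Gjc1 20.4, Ryr2 11.5 and Kcnh2 16.0. Sln, the gene of sarcolipin, and Casq2, the gene of cardiac calsequestrin, had none, though Casq2 had a peak of fold 3.53 in replicate 1's own list and of 3.09 in the pooled list. Of the signalling genes, 24 of 25 had a peak (adjusted exact p = 0.00088), with Vegfa at 26.7, Igf1r at 25.2, Igf2 at 23.8 and Erbb2 at 23.3, and Tdgf1 without. The natriuretic peptide gene Nppa, a chamber marker, had a modest peak of 4.18.

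Lists of the other cell layers of the heart gave calls in part. Of the endothelial and endocardial genes, 24 of 25 had a peak (adjusted exact p = 0.00088), with Fli1 at fold 16.9, Lmo2 at 16.7, Tal1 at 16.6, Notch1 at 13.5 and Pecam1 at 6.29, and Flt4 without. Of the cushion mesenchyme genes, 22 of 24 had a peak (adjusted exact p = 0.00667), with the matrix genes Vcan at 20.3, Fn1 at 17.4 and Fbn1 at 12.3 and the receptor gene Pdgfra at 12.2, and Lum and Postn without. Of the epicardial genes, 15 of 18 had a peak, which did not pass the test (adjusted exact p = 0.165). Bnc2 (11.1), Tcf21 (11.0), Tbx18 (9.41) and Wt1 (4.75) were among them, and Gpm6a, Muc16 and Upk1b had none. Of the second heart field and outflow tract genes, 18 of 20 had a peak (adjusted exact p = 0.0248), with Ptch1 at 24.5, Wnt5a at 21.1, Plxna2 at 14.7 and Foxc2 at 13.6; Isl1, a factor of second heart field progenitors, had 7.21. That call ended with the 5'-most start only (adjusted exact p = 0.143), with −log10 q of at least 5 (0.214) and with peaks found in both replicates' own lists (0.0809). It also ended against random lists matched on promoter CpG ratio, of which 84.2% of genes had a peak (adjusted p = 0.63, n = 20 genes).

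Energy and growth genes were acetylated alongside. All 19 glycolysis genes had a promoter peak (adjusted exact p = 0.000816), among them Gapdh (34.0), Ldha (32.3), Eno1 (27.7) and Eno3 (32.3, at a peak shared with Pfn1, with 31.5 in replicate 1 and only 7.72 in replicate 2). Of the fatty acid oxidation genes, 19 of 20 had a peak (adjusted exact p = 0.00584), led by Eci1 (20.4), and Cd36 had none. All 25 cell cycle genes (Ccnd2 26.9, Mki67 26.0, Cdk1 25.6, Ccnd1 21.5) and all 25 ribosomal protein genes (Rps19 40.2, Rpl19 39.8, Rps6 36.1, Rps14 34.1) had a peak (adjusted exact p = 7.01e-05 for each). Against CpG-matched lists the calls for fatty acid oxidation (adjusted p = 0.134, n = 20 genes), cell cycle (0.424) and ribosomal protein genes (0.0939) ended. Genes of mature striated muscle had peaks at 15 of 18, which did not pass the test (adjusted exact p = 0.165). In replicate 1's own list, that is without replicate 2, they did (adjusted exact p = 0.0174). The list exceeded the 42.7% of CpG-matched lists (adjusted p = 0.0006, n = 18 genes). Fhl2 (15.8), Pgam2 (14.2), Adrb1 (11.1) and S100a1 (8.86, shared with S100a13) led this list, and Ckmt2, Myom2 and Rpl3l had none, though Rpl3l had peaks of 3.08 and 3.22 in the replicates' own lists.

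Genes of other lineages had fewer promoter peaks. Over distinct genes, 174 of 185 heart-list genes (94.1%) and 62 of 161 other-lineage genes (38.5%) had a replicated promoter peak (Fisher's exact test, two-sided p = 1.06e-30). This test was not matched on promoter CpG ratio, so part of the difference may go with CpG content. CpG-matched shares ran from 50.3% to 84.7% for the heart lists and from 26.4% to 86.1% for the other-lineage lists. Hepatocyte genes had 3 of 20 (adjusted exact p = 4.96e-05), and all 3 peaks also lay at another gene's start: Foxa3 with Sympk (fold 19.3), Apoh with Prkca (15.4) and Trf with Gm20425 (3.81). Alb, Afp and Ahsg had none. Skeletal muscle genes had 5 of 23 (adjusted exact p = 0.000102), and the strongest, at Mylpf (18) and Actn3 (15.1), lay at the starts of Tbc1d10b and Zdhhc24 as well. Tnni2 (5.08) and Tnnt3 (3.63) had weaker peaks and Myod1, Acta1, Chrna1 and Chrnd none. The difference from other genes was -42.6 percentage points. In replicate 2's own list (without replicate 1) it was -22.8 (adjusted exact p = 0.0399). In replicate 1's own list (without replicate 2) it was -19.2 and the call ended (adjusted exact p = 0.0971). Both lists hold more peaks than the replicated list, so such changes need not come from the replicate left out.

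Germline and pluripotency genes had 3 of 20 (adjusted exact p = 4.96e-05), at Gdf9 (21.7, shared with Uqcrq), Dazl (7.94) and Spo11 (4.55), with none at Bmp15, Ddx4 or Dppa3. The difference from other genes was -49.3 percentage points, and -36.3 without replicate 1 (adjusted exact p = 0.00252), where Prm1 (4.0), Pou5f1 (3.2) and Tdrd1 (2.52) also had a peak in replicate 2's list, and -47.1 without replicate 2. Macrophage and leukocyte genes had 3 of 18 (adjusted exact p = 0.000113), at Coro1a (5.58), Cd14 (5.10) and Spi1 (3.97), with none at Adgre1, Aif1 or C1qa, though Aif1 had peaks of 3.25 and 2.49 in the replicates' own lists. The difference from other genes was -47.7 percentage points, and -33.0 without replicate 1 (adjusted exact p = 0.00849) and -28.2 without replicate 2 (adjusted exact p = 0.0307). The macrophage call ended against CpG-matched lists, of which 32.4% of genes had a peak (adjusted p = 0.222, n = 18 genes), while the hepatocyte, skeletal muscle and germline calls stayed (matched shares 42.2%, 45.2% and 60.6%). Of 1135 olfactory receptor genes, 1 had a peak (0.0881%), against 67.8% of all other genes but only 10.5% of CpG-matched lists, so most of that gap goes with promoter CpG content.

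Neural crest genes had 11 of 18 (adjusted exact p = 0.843), neuronal genes 12 of 25 (adjusted p = 0.13) and foregut and lung endoderm genes 10 of 18 (adjusted p = 0.508), none past the threshold. Their peaks were weak, with medians of fold 4.19, 3.47 and 3.98 against 12.8 for all genes with a promoter peak. Mpz had 25.4, at the start of Sdhc, Phox2a 7.94, Ednrb 6.75 and Sox10 3.23 in the first list. Elavl4 had 11.9 and Gabra1 6.53 in the second, and Grhl2 10.4 and Spint2 9.44 in the third. Foxd3, Pax3, Dbh, Gad2, Neurod1, Neurog1, Cdx2, Cldn4 and Cldn6 had none. With −log10 q of at least 5 all 3 lists were below other genes (adjusted exact p = 0.00371, 9.9e-06 and 0.00371). Against CpG-matched lists the neuronal (adjusted p = 0.0006, n = 25 genes) and foregut lists (0.0192, n = 18 genes) were lower.

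Erythroid genes had 15 of 19 (adjusted exact p = 0.267), led by Tfrc (21.6), which encodes the transferrin receptor, Klf1 (15.4), Nfe2 (10.4) and Gypa (8.63), with Hbb-y at 4.19. Gata1, Hba-a2 and Hbb-bs had none. CpG-matched lists had peaks at 26.4% of their genes, and the erythroid list exceeded them (adjusted p = 0.0006, n = 19 genes). The adult alpha- and beta-globin genes are near-identical copies, so a peak or its lack at a single copy is uncertain.

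**Figure D2:**
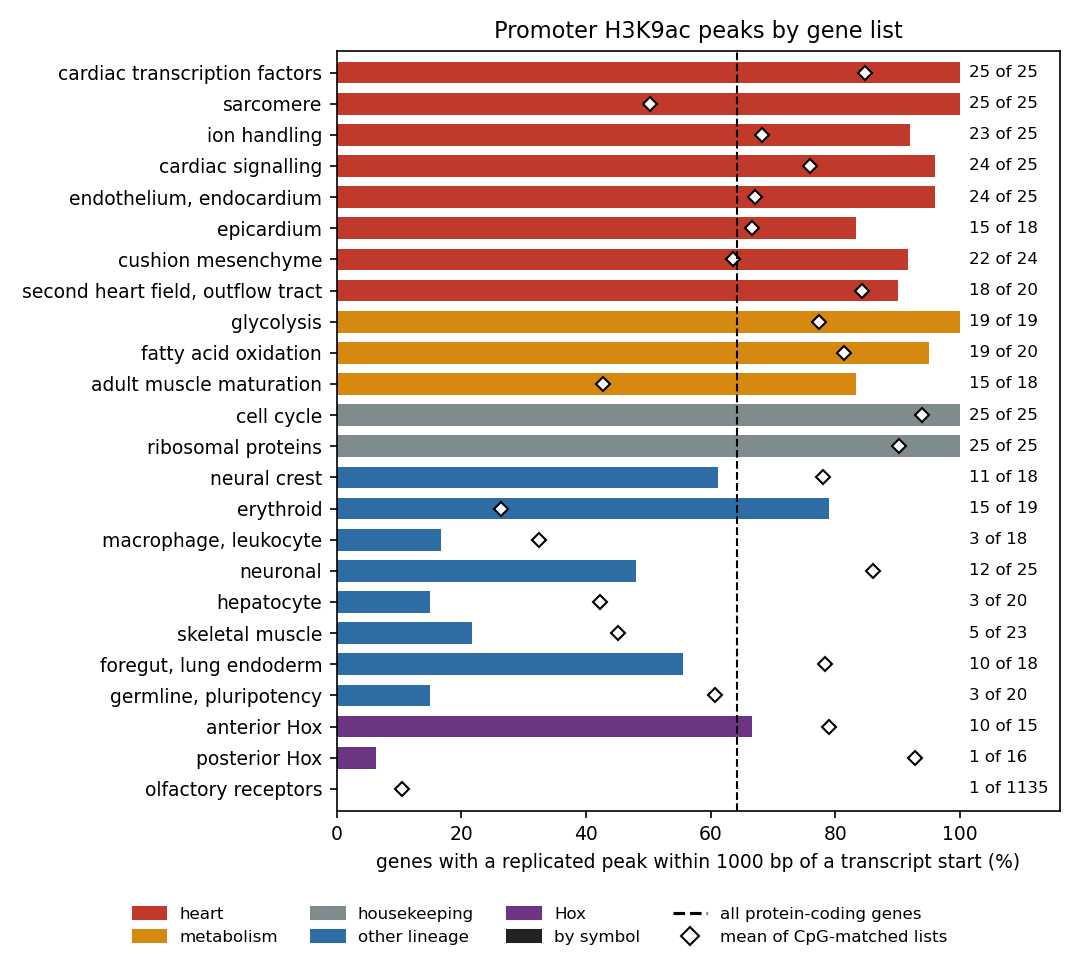
Percent of each gene list with a replicated peak within 1000 bp of a transcript start (bars, coloured by kind of list; counts at the right). Diamonds are the mean of 10000 random lists matched on promoter CpG ratio, and the dashed line is the share of all protein-coding genes (64.3%). Cardiac transcription factor and sarcomere genes reach 100%, and posterior Hox genes 6.25%.

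Anterior and posterior Hox genes differed. Of the anterior Hox genes 10 of 15 had a promoter peak (66.7%) and of the posterior ones 1 of 16 (6.25%), and the difference passed Fisher's exact test (two-sided p = 0.000635). That test takes genes as independent, yet listed Hox genes can be close neighbours, as Hoxb2, Hoxb3 and Hoxb4 are on chromosome 11. Hoxb2 (fold 13.1), Hoxb3 (6.93), Hoxb4 (6.82) and Hoxa5 (5.97) led the anterior list, and Hoxa3, Hoxb1 and Hoxb5 had none, though Hoxb5 had peaks of 4.72 and 3.12 in the replicates' own lists and Hoxb1 of 3.28 in replicate 2's. The only posterior gene with a replicated peak was Hoxd9 (3.43), and Hoxa10, Hoxa11 and Hoxa13 were among those without. In replicate 1's own list Hoxa9 (3.26), Hoxc9 (3.67) and Hoxc13 (2.95) had weak peaks too, and in replicate 2's no posterior gene had one. The posterior difference from other genes was -58.1 percentage points, and -66.3 without replicate 1 and -42.1 without replicate 2 (adjusted exact p = 0.00153). The posterior list was below all other genes (adjusted exact p = 2.49e-05) and the anterior list did not differ from them (adjusted p = 1).

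The height and the length of promoter acetylation ranked the gene groups differently. Ribosomal protein genes had the highest peaks (median fold 22.7) and glycolysis genes followed (18.4), and both exceeded random lists of genes with a promoter peak, whose median was 12.8 (adjusted p = 0.0011 with n = 25 genes and 0.0152 with n = 19 genes, 10000 random lists). Cardiac transcription factor genes had a median fold of 16.0 (adjusted p = 0.121, n = 25 genes) but the longest acetylation. A median of 5731 bp within 5000 bp of their 5'-most start was covered by peaks, against 1695 bp in random lists (adjusted p = 0.00088, n = 25 genes). Against ribosomal protein genes the length was greater (5731 bp and 2546 bp, permutation p = 2e-05, the smallest it can give) and the fold lower (permutation p = 0.0207); this pair of lists was chosen after the values were seen. In fold, cardiac transcription factor genes were called higher than random lists without replicate 2 (percentile 99.4 against 96.1), and without replicate 1 so were sarcomere (99.9 against 96.0) and cell cycle genes (99.425 against 88.6). Sarcomere genes were also called higher against CpG-matched lists (percentile 99.96).

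Sarcomere genes had a median of 4011 bp and ion handling genes 3658 bp (adjusted p = 0.00088 for each, n = 25 and n = 23 genes), glycolysis genes 3186 bp (0.00088), signalling genes 2869 bp (0.00147), cell cycle genes 2713 bp (0.00377), cushion genes 2583 bp (0.0066) and ribosomal protein genes 2546 bp (0.0066). Endothelial genes (1957 bp, adjusted p = 0.454, n = 24 genes), epicardial genes (1567 bp, 0.861) and second heart field genes (1642 bp, 0.861) did not differ from random lists. Fatty acid oxidation genes (1675 bp), mature muscle genes (1182 bp), erythroid genes (1906 bp), anterior Hox genes (1832 bp), hepatocyte (1516 bp), skeletal muscle (1563 bp), foregut (1069 bp), germline (727 bp) and macrophage genes (839 bp) did not either. Neural crest (663 bp, adjusted p = 0.0066, n = 11 genes) and neuronal genes (334 bp, 0.00088, n = 12 genes) were shorter. Without replicate 2 the neural crest call ended (percentile 2.045 against 0.135) and erythroid genes were called longer (99.1 against 75.3), as they were against CpG-matched lists (1906 bp and 820 bp, adjusted p = 0.0196, n = 15 genes). In the replicates' own lists 5 to 7 lists were shorter, macrophage and skeletal muscle genes in both, and none with −log10 q of at least 5.

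By gene, Gata6, a zinc finger factor of cardiac mesoderm, was covered over 9962 bp on chromosome 18 around position 11052064, then Tnrc18 (9926 bp), Meis2 (9804 bp), Irf2bp2 (9205 bp), Mef2d (9170 bp), Hand2 (9099 bp), Actc1 (9083 bp), Tbx5 (8994 bp), Tbx20 (8933 bp) and Kdm6b (8908 bp). Nkx2-5 had 8795 bp, the myosin heavy chain genes Myh7 8154 bp and Myh6 6906 bp, and Tnnt2 4930 bp. Mef2c (fold 11.9) and Pecam1 were listed at 0 bp because their promoter peaks lay at annotated starts away from the 5'-most start. Lower fold than random lists was found for endothelial (7.33), epicardial (6.41), cushion (7.54), second heart field (6.87), mature muscle (6.10), neural crest (4.19), erythroid (5.89), neuronal (3.47), foregut (3.98) and anterior Hox genes (5.17), and of these 10 lists 6 stayed lower against CpG-matched lists. The endothelial and epicardial calls ended without replicate 1 (percentiles 2.085 and 2.63, against 0.21 and 0.445), and the cushion and second heart field calls without replicate 2 (2.045 and 2.15, against 0.37 and 0.2).

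**Figure D3:**
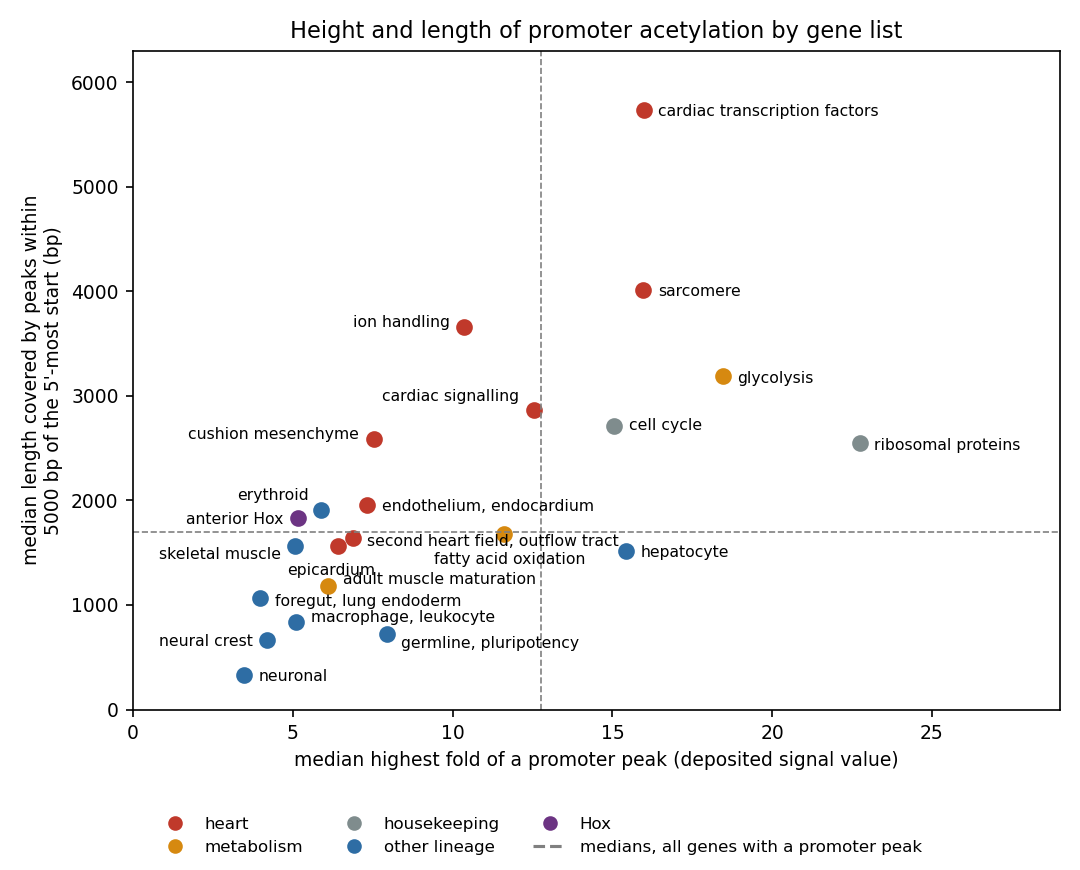
Median highest fold of a promoter peak (horizontal axis, deposited signal value) and median length covered by peaks within 5000 bp of the 5'-most start (vertical axis, bp) over the genes with a promoter peak of each list (points, coloured by kind of list; lists with under 3 such genes are left out). Dashed lines are the medians of all genes with a promoter peak, 12.8 and 1696 bp; cardiac transcription factor genes stand at 16.0 and 5731 bp and ribosomal protein genes at 22.7 and 2546 bp.

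Distal peaks gathered around cardiac regulators. The 25 cardiac transcription factor genes had a mean of 7.6 distal peaks each, against 1.2 in random lists matched on the length of the surrounding interval (adjusted p = 0.0024, 10000 random lists, n = 25 genes). Signalling genes had 4.28 against 1.08 (adjusted p = 0.0156, n = 25 genes) and sarcomere genes 3.36 against 0.6 (adjusted p = 0.0128). These random lists were drawn from all protein-coding genes, of which 64.3% had a promoter peak, against all 25 cardiac transcription factor genes. Part of the difference may thus go with having a promoter peak. Lists drawn only from genes with a promoter peak were not tested for distal peaks. Ion handling (3.28, adjusted p = 0.0693, n = 25 genes), endothelial (2.88, 0.0693) and glycolysis genes (1.84, 0.0693) did not pass, and olfactory receptor genes had fewer than random lists (0.0132 against 0.334, adjusted p = 0.0024). Without replicate 1 ion handling and glycolysis genes passed (percentiles 99.655 and 99.505), and without replicate 2 endothelial genes did (99.5). With −log10 q of at least 5 the signalling call ended (adjusted p = 0.109, n = 25 genes). Among cardiac transcription factor genes Tead1 had 31 distal peaks, Prdm16 26, Gata5 20, Gata4 19, Nkx2-5, Tbx5 and Mef2d 12 each, and Gata6 10. Hand2 had 3, and Isl1, Srf and Zfpm2 had 0, so the mean of this list was carried by part of its genes. Adjacent peaks were not merged, so a broad acetylated stretch can count as several distal peaks. Inside Gata4, for example, a replicated peak ended at 63233541 and the next began at 63233579. Distal peaks close enough to a 5'-most start also add to acetylated length, so the distal and length results overlap in part. Counts of merged peaks were not tested.

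The genes with the most distal peaks were Gse1 (77), Zmiz1 (56), Casz1 (44), Tns1 (41), Smad6 (38), Zfpm1 (38), Sh3pxd2a (34), Ahdc1 (33), Tspan9 (32) and Tead1 (31). Casz1 is a zinc finger factor needed in heart development, and Smad6 an inhibitor of BMP signalling. By fold in the replicated list, the strongest distal peaks lay nearest to Zfp869 (fold 26.9), Chd2 (26.0), Ptma (23.6), Mos (23.1), Prdm2 (23.1), Gata4 (22.6), Pum2 (22.4), Tex44 (21.9), Spag6 (20.4) and Slc38a2 (19.8). The peak at Gata4 lay inside the gene and overlapped an annotated exon and UTR, at 63237855 to 63241979 on chromosome 14 and 5331 bp from the nearest start, with fold 36.7 in replicate 1 and 23.6 in replicate 2, the highest of the 10 in both replicates' own lists. The peak at Prdm2 overlapped an exon of that gene, and the other 8 overlapped no annotated gene. The Chd2 peak was 76661 bp from that gene's nearest start.

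**Figure D4:**
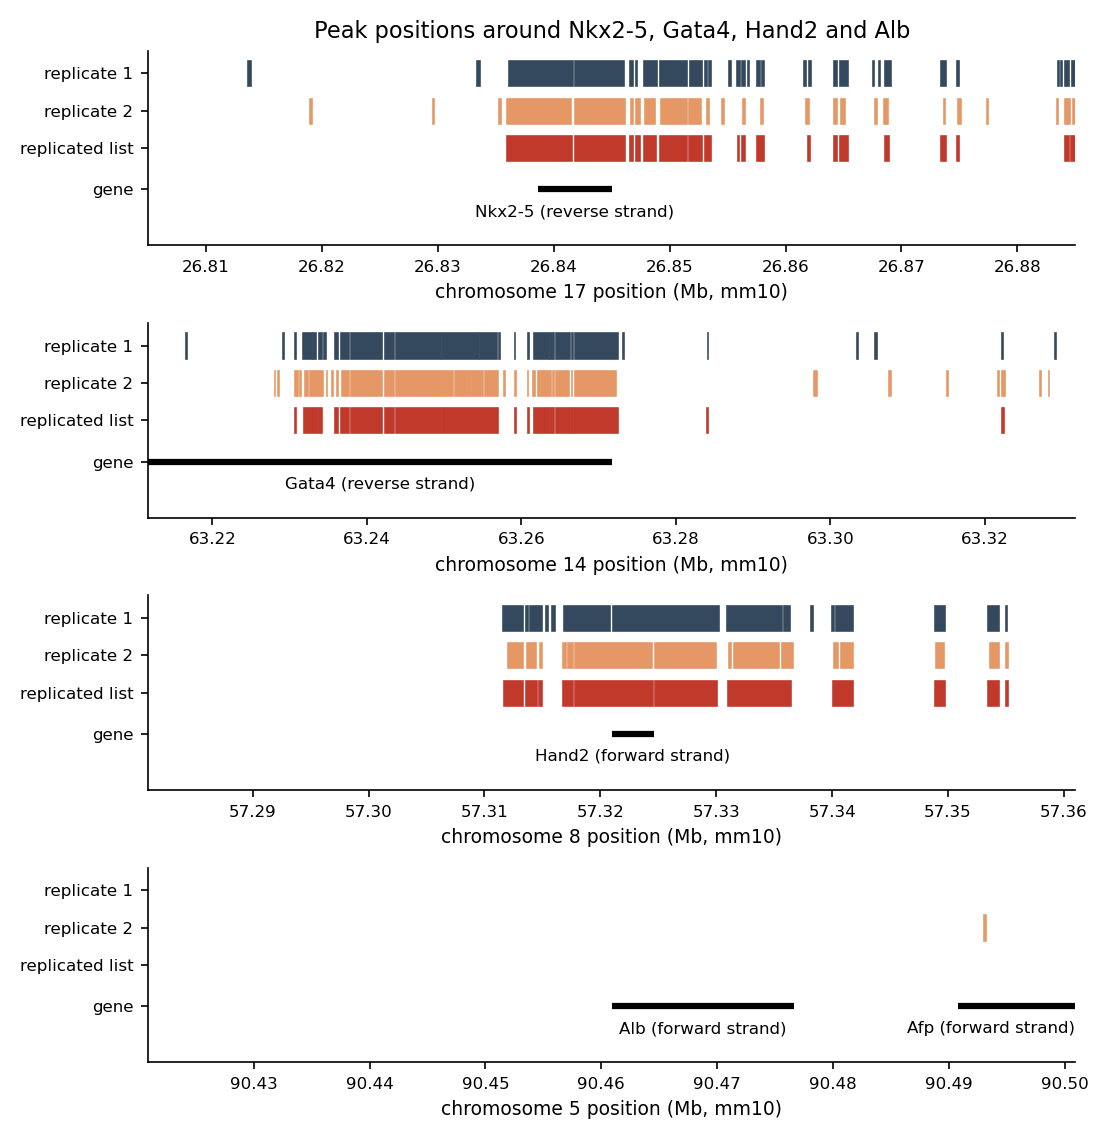
Positions of peaks (boxes; rows from the top are replicate 1, replicate 2 and the replicated list) and of protein-coding genes (black bars) around Nkx2-5, Gata4, Hand2 and Alb; horizontal axes are mm10 positions in Mb. Peaks of both replicates cover Nkx2-5, Hand2 and the 5' part of Gata4, and the Alb window holds a single replicate 2 peak, inside Afp.

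At Nkx2-5, on the reverse strand of chromosome 17 (26838664 to 26845009), the replicated peak with the highest fold (29.3) ran from 26835900 to 26841601 over exons and UTR of the gene and its internal start. The peak over the 5'-most start was weaker (9.41, at 26841736 to 26846149). A further peak of fold 18.3 lay at 26849082 to 26851483, upstream of the gene. At Hand2, on chromosome 8 (57320983 to 57324633), the peak of fold 36.2 ran from 57317761 to 57324516 over the gene and over Hand2os1, and a peak of 26.5 followed to 57330065. The strongest promoter peak of Gata4 (30.9, at 63243591 to 63249600) lay at an internal annotated start. The promoter peak of Tbx5 was 12430 bp long (119828675 to 119841104 on chromosome 5). Around Alb, from 90420897 to 90500896 on chromosome 5, no replicated peak was found.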

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

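The settings with peaks found in both replicates' own lists and without genes sharing a peak were chosen after the results were seen. No result reversed. Of the values of the main comparisons under other settings, 404 kept their side of the threshold or stayed close, 14 were weaker, 17 stronger and 21 moved. Among the 404 were the heart against other-lineage difference (44.8 to 68.2 percentage points), that between anterior and posterior Hox genes (40.4 to 86.7 points) and the calls for cardiac transcription factor and sarcomere genes for share, length and distal peaks. Overlap of replicate 1 and replicate 2 peaks was 40.5% and 42.0% with at least 50% of the first peak, 32.6% and 29.2% with 50% of both, 65.5% and 90.2% with −log10 q of at least 5, and 79.5% and 88.7% among the 20000 strongest; with −log10 q of at least 2 it was 60.9% for replicate 2. Spearman's rho was 0.828 with 50% of the pooled peak, 0.805 with −log10 p and 0.835 with −log10 q of at least 2. With 50% overlap 51.3% of pooled peaks were found in both replicates, and 85.4% of those with −log10 q of at least 2 were kept. The share of peaks at promoters was 42.1% within 500 bp, 55.5% within 2500 bp, 70.5% with −log10 q of at least 5, 37.1% in the pooled list, 31.4% to 32.1% in a replicate's own list and 51.8% for peaks in both. In differences of percentage points between a list and other genes, the second heart field call ended with −log10 q of at least 5 (15.6), the 5'-most start (19.6), peaks in both replicates (22.0) and CpG matching (5.79); the neuronal list was called lower with 500 bp (-27.5), −log10 q of at least 5 (-47.5), the 5'-most start (-28.5), peaks in both replicates (-27.1) and CpG matching (-38.1). With −log10 q of at least 5 the neural crest and foregut lists were called lower (-37.3 each). CpG matching ended the calls for fatty acid oxidation (13.7), cell cycle (6.07), ribosomal (9.87) and macrophage genes (-15.8), and gave calls for mature muscle (40.7), erythroid (52.6) and foregut genes (-22.8). Without a replicate, mature muscle genes ranged from 22.6 to 27.4 and skeletal muscle genes from -22.8 to -19.2. Lists of higher fold numbered 3 to 4 without a replicate, and of lower fold 6 with CpG matching. Lists of shorter acetylation numbered 1 with 10000 bp, 0 with −log10 q of at least 5 and 5 to 7 without a replicate. The cushion length call ended with 10000 bp (percentile 98.965) and the signalling distal call with −log10 q of at least 5 (percentile 99.205). Lists with more distal peaks numbered 4 to 5 without a replicate, where ion handling genes stood at percentiles 99.295 to 99.655 and endothelial genes at 98.92 to 99.5. Stricter filters leave fewer peaks, a replicate's own list holds more peaks than the replicated list, and CpG matching changes the background. Otherwise the cause was not tested. Depth is unknown, so weak peaks cannot be graded by it.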

Other observations

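The tests of weak acetylation at CpG-rich promoters, of liver cells and of circulating erythroid cells were chosen after the result was seen, as was the use of 95% intervals in reading the neighbouring-start, RefSeq and motif tests. Reading the unshared-peak test by the share of peaks under its bound was also chosen after its values were seen.

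Of the binding motifs of cardiac factors, some were in more distal peaks than GC-matched windows, and others not. The MEF2 motif, bound by factors of muscle differentiation, was in 5.32% of 17100 distal windows and 2.62% of control windows (ratio 2.03, 95% interval 1.82 to 2.27, Fisher's exact test, adjusted p = 7.87e-37). The NKX2 motif was in 10.7% and 8.98% (ratio 1.20, interval 1.12 to 1.28, exact adjusted p = 1.73e-07), the TEAD motif in 18.3% and 16.8% (1.09, 1.04 to 1.14, 0.000561) and the GATA motif in 50.8% and 46.9% (1.08, 1.06 to 1.11, 4.04e-12). The T-box motif did not differ past the threshold (ratio 0.979, exact adjusted p = 0.81), nor did SRF (1.15, 0.0657). The ETS motif, bound by endothelial factors among others, was in 1.57% and 1.05% (1.5, exact adjusted p = 5.99e-05). This motif holds a CpG, and control windows were matched on GC content but not on CpG ratio, so its excess may go with CpG content. An E-box used by HAND factors was in fewer peak windows (0.963, exact adjusted p = 0.0168). The hypothesis that distal peaks mark regions bound by the 5 cardiac families asked for 3 motifs with a ratio over 1.1, and 2 had one. The GATA and TEAD intervals reach over 1.1, so the count is not settled within its error, and with the ratios alone the bound was missed. Of the comparison motifs, HNF4 had a ratio of 1.05 (exact adjusted p = 0.849), and SOX10 and RFX were in 3 windows or fewer, too few to compare.

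Promoters of erythroid genes held peaks more often than CpG-matched lists (15 of 19 genes against 26.4%). Neighbouring genes are argued against, since 6.67% of the 15 peaks (1 of 15, exact 95% interval 0.169% to 31.9%) lay at the start of a non-erythroid gene, under the 50% that this explanation needs. Liver tissue with hepatocytes enough to mark their promoters is argued against too. Of hepatocyte genes, 15% had a peak against 42.2% of CpG-matched lists, and of the abundant liver genes Alb, Afp, Apoa1 and Ttr 0 of 4 had one. Replicate 2's own list held a peak of fold 3.20 inside Afp, over 1000 bp from its starts. Liver cells of other kinds, or too few to mark these promoters, were not tested. Circulating erythroid cells in the heart tissue are neither supported nor excluded. The 73.7% of the list (14 of 19) with a peak and no neighbouring start restates the pattern, as do the peaks of the embryonic globin genes in that list, and no other list holds any of the 19 genes. Tfrc is used by many dividing cells and near-identical globin copies are uncertain. Cells of other kinds count here as a technical source, and no biological explanation was tested, as the design has 1 group.

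Of the 62 other-lineage genes with a promoter peak, 19.4% (12, exact 95% interval 10.4% to 31.4%) had it at another gene's start, against 25.3% of heart-list genes (Fisher's exact test, p = 0.389), which argues against neighbouring genes as the main source. The 12 had a median fold of 12.8, as had all genes with a promoter peak. The 50 others had a median of 4.19, which may come from a few cells of those lineages or from low acetylation of CpG-rich promoters in general. The second reading asked for a median CpG ratio of at least the 0.603 of all genes with a promoter peak. The value was 0.526, and its 95% interval (0.305 to 0.614) reaches over that bound, so the miss excludes nothing. It lay above the median of genes without a promoter peak (0.173, interval 0.170 to 0.176). Over the 50 genes together both readings give weak peaks in a mixed tissue, so this test cannot tell them apart. By list the shares differed. Erythroid genes with a peak and no neighbouring start made up 73.7% of their list (exact 95% interval 48.8% to 90.9%). In CpG-matched lists the share was 26.4%, which argues against CpG-rich promoters in general as the only source for that list. Neuronal (48% against 86.1%) and foregut genes (55.6% against 78.3%) lay below their CpG-matched shares. No biological explanation was tested, for want of a second group.

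Strong distal peaks, 236 with a fold of 10 or more, could be promoters that the annotation lacks. RefSeq starts lay within 1000 bp of 19.5% of them (46, exact 95% interval 14.6% to 25.1%), against 6.57% of other distal peaks, so such starts leave most of them unaccounted for. Their median CpG ratio was 0.570 against 0.252, and 46.6% against 5.28% were over 0.6, a value between the bounds set for CpG islands as the source, which stays open. In all, 132 (55.9%) were at a RefSeq start or over 0.6, and 104 were neither, among them the exon peak of Gata4 (fold 22.6, CpG ratio 0.412) and peaks near Irf2 (19.4), Snx5 (18.8) and Qk (17.4). These last 3 genes were chosen after their values were seen, and no biological explanation was tested.

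Peaks of a single replicate had median folds of 0.688 and 0.745 times those of shared peaks, above the bound set beforehand for weak peaks near the calling threshold. Only 2.34% and 0.309% of all peaks lie under that bound, so it could hardly have been met and decides nothing. By count, 88 of 40941 unshared peaks in replicate 1 and 34 of 46224 in replicate 2 had a fold of 6 or more. Almost all unshared peaks were thus under fold 6, but their nearness to the calling threshold was not tested. The acetylated length of cardiac transcription factor genes (median 5731 bp) stood at percentile 100 of lists matched on the number of annotated starts (median 1617 bp), and these genes had a median of 3 starts against 4, which argues against more starts as the source.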
